A study of Mus musculus with 12 samples.

How the data were processed

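The deposited table held 35275 mouse genes and 12 lung libraries, 3 per age at 3, 6, 12 and 24 months. Values were in counts for each library, per the file headers, and these reads per gene were the only values tested. The deposited table also held FPKM for each library and each age, and FPKM recomputed from the reads and gene lengths matched 235411 of 235411 values within 1e-06. Signal values, computed by the authors for each comparison, were taken as means per age of scaled reads and were not used, and 2 further columns of 3-month signal, from the other 2 comparisons, were set aside. Log2 fold changes of 3 comparisons against 3 months were deposited by the authors. Their p values (p_value) were computed by the authors and deposited, and the tool behind them is not given in the sources used here. The submitters' notes name TopHat, STAR 2.5 and HTSeq 0.6.1 without roles, and build mm10. Whether reads on either strand were counted, how reads on overlapping genes or paralogs were assigned, and the strandedness of the libraries are not given in the sources used here. The labels describe minced lungs kept in RNAlater, RNeasy extraction, an RNA integrity check on an Agilent instrument, and the NEBNext Ultra kit. No integrity values, batch, date or lane of sequencing were given.

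Gene reads per library were 20.9, 18.9 and 16.5 M at 3 months, 15.3, 17.4 and 19.6 M at 6 months, 21.2, 17.0 and 16.1 M at 12 months, and 14.7, 18.0 and 16.4 M at 24 months. Genes with a read numbered 20175 to 20625 at 3 months, 20032 to 20237 at 6 months, 19539 to 20020 at 12 months and 17533 to 18513 at 24 months. Of the gene IDs, 126 shared a symbol with another, and gene IDs were kept apart.

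Groups, comparisons, tools, gene lists and alternatives were chosen before the data were examined, except where stated. Genes were filtered with filterByExpr on the 4 ages, which left 16042. Libraries were scaled with TMM. The test was the edgeR quasi-likelihood F test with robust dispersions on all 12 libraries (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Comparisons were 24, 12 and 6 against 3 months, 12 against 6, 24 against 12, any difference among the ages, and a trend on log2 age. Each library was 1 mouse and 1 unit of the test. Benjamini-Hochberg adjustment was made within each comparison, and genes with an adjusted p under 0.05 were called. CPM used TMM library sizes, except that Xist was also given as CPM of all gene reads. Fold changes are from the edgeR fit, and their SE was derived from the fold change and the F statistic. For genes with 0 reads at an age only levels are given, and for 1 to 3 reads the ratio of pooled reads over library totals with a 95% exact binomial interval. Such ratios and intervals leave out the spread between mice and any correction for GC content and gene length.

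The gene lists numbered 47 and covered cell types, pathways and tissues next to the lung. Of these, 46 had at least 4 tested members and were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, with camera with an estimated correlation, and with fry. Counts of list members called are given with adjustment over all genes and adjusted over the list alone. Immunoglobulin V segments, Y-linked genes and ribosomal proteins were grouped by symbol.

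Genes named in the text followed a rule. At 24 against 3 months the 10 largest folds each way were named, and in the other comparisons the 5 largest each way. Such genes needed an adjusted p under 0.05, a mean CPM of at least 1, a symbol, and no overlap between the 3 mice of each age. Up to 4 members with the smallest p of a described list were named, and 15 genes were fixed in advance. V, D and J segments, numbered gene models, Riken clones and pseudogenes were left out of single gene naming, except where a comparison had 6 or fewer calls with a tool. Jchain is Igj in the deposited table.

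The alternatives were RLE size factors in edgeR, DESeq2 1.42.0, limma voom, no filter, a mean CPM of at least 1, mouse number as a block, only the 6 mice of a pair of ages, age on a linear scale, and leaving out each mouse in turn. Alternatives written for a table without counts were not needed. After the data were seen, alternatives were added that remove each library's smooth on GC content, or on GC content and gene length, as an offset (mgcv 1.9.3), that leave out the 24-month libraries, or that join these. GC content came from GENCODE M21 transcripts for 97.8% of gene IDs and for 15949 of the tested genes. Length was the deposited gene length. A mouse number shared between ages was not treated as a pair, and the residual r of the 18 same-number pairs had a median of -0.05, with 5 over 0.1. The 3 such pairs of 3 and 6 months had 0.119 to 0.242, and the 6 other pairs of these ages -0.155 to -0.014, so the fit with mouse number as a block is given beside the calls that it ended. Residuals were deviations from the age mean, so positive r in same-number pairs push the r of the other pairs toward negative values.

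The steps were tested on simulated data drawn from the mean proportions and dispersions of genes over all 12 libraries, with 200 changed genes per comparison. The edgeR test recovered 0 to 10% of genes with a fold of 1.5, 26 to 44% at a fold of 2, 84 to 96% at 4 and 94 to 100% at 8 in the pairwise comparisons, with 5 to 10 false calls. With the GC and length trend of the real libraries added to the simulation, false calls at 24 against 3 months numbered 12815 without and 7 with the correction. The simulated trend was the smooth that the correction fits, so this cannot show how well that smooth fits the real trend. All 4 shifted lists and no other list were called. Genes were simulated as independent, so this does not test the lists where genes are correlated.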

Results

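Lung RNA from 12 male wild-type C57Bl/6J mice was compared at 3, 6, 12 and 24 months of age, with 3 mice and 3 poly(A) RNA-seq libraries per age. Reads per gene were available for 35275 genes, and 16042 genes held enough reads to be tested. Libraries held 16.5 to 20.9 M gene reads at 3 months, 15.3 to 19.6 M at 6 months, 16.1 to 21.2 M at 12 months and 14.7 to 18.0 M at 24 months. Below, levels are CPM as mean ± SD of 3 mice, and fold changes are log2 values ± SE with p values adjusted over the 16042 genes. Coordinates refer to mm10.

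The 24-month libraries stood apart from the other 9. The first principal component carried 86.6% of the variance and separated the 24-month mice, and the correlation of log2 CPM between 3-month and 24-month libraries was 0.602 to 0.779, against 0.983 to 0.994 among 3-month libraries. The mean annotated GC content of genes, weighted by their reads, was 54.4, 54.7 and 56.1% in the 24-month mice and 50.4 to 51.8% in the other 9. Mitochondrially encoded reads made up 0.443 to 0.629% of reads at 24 months, 1.65 to 2.14% at 3 and 6 months, and 3.12% in 12-month mouse 3. The 10% of genes with the lowest GC content had a median log2 fold change of -2.66 at 24 against 3 months, and the 10% with the highest GC content 2.26. A joint smooth on GC content and gene length gave 74.5% of the variance of these fold changes, 41.8% at 12 against 3 months and 18.8% at 6 against 3 months. A correction that removes this smooth from each library was therefore added after the data were seen, and its results stand beside many of the uncorrected ones. A fold change printed alone is without the correction.

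**Figure D1:**
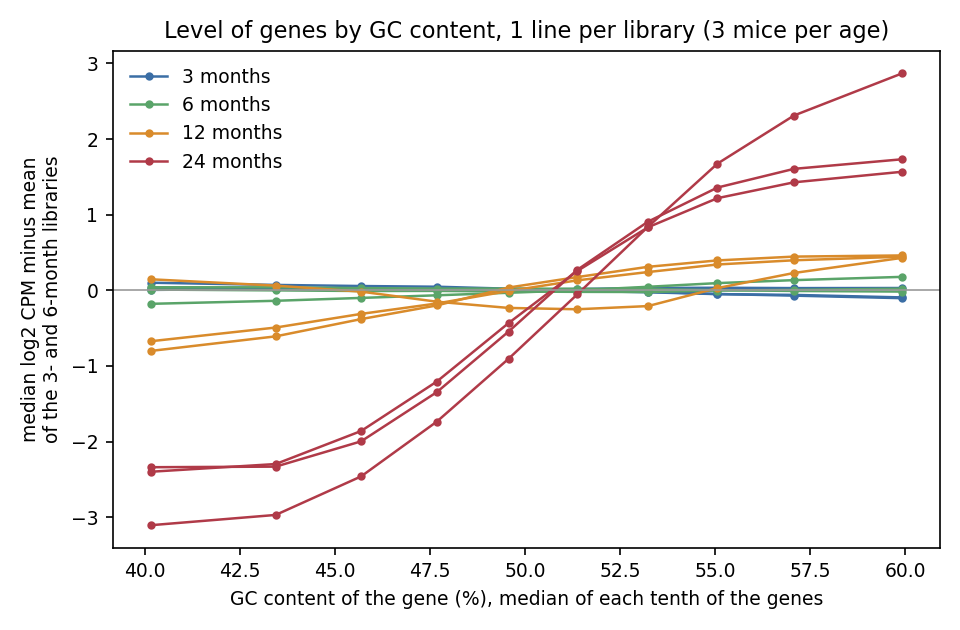
Genes were put into 10 bins by GC content (x axis, median % of each bin), and the y axis gives their median log2 CPM minus the mean of the 3- and 6-month libraries, with 1 line per library coloured by age. The 24-month lines run from -3.11 to -2.34 in the lowest bin and from 1.57 to 2.87 in the highest. The lines of 12-month mice 1 and 2 go from -0.67 and -0.80 in the lowest bin to 0.44 and 0.46 in the highest. The line of 12-month mouse 3 starts at 0.15, is at -0.25 in the 6th bin and ends at 0.43.

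Most genes of antibody-producing cells rose between 3 and 24 months. Ighm (chr12:113418950-113422730), the constant region of IgM, rose from 103 ± 12.8 CPM at 3 months to 2106 ± 550 CPM at 24 months (log2 4.35 ± 0.38, adjusted p = 1.3e-07). Igkc, the kappa light chain, rose from 57.6 ± 12.9 to 985 ± 243 CPM (4.09 ± 0.37, adjusted p = 1.7e-07). Igj, the J chain that joins IgM and IgA units, rose from 8.84 ± 2.82 to 113 ± 40.3 CPM (3.68 ± 0.40, adjusted p = 7.7e-07). Of the 18 tested genes of plasma cells and immunoglobulin constant regions, 17 rose and 1 fell (17 and 1 adjusted over the list alone), with a median log2 fold change of 3.89. The list passed the camera test (adjusted p = 0.000823), and had an adjusted p = 0.974 with an estimated correlation. Igha, the IgA constant region (4.11 ± 0.37), and Mzb1, a chaperone of antibody secretion (4.25 ± 0.38), were among the members that rose, and Prdm1, a transcription factor of plasma cell formation, fell (-2.72 ± 0.25, and -0.50 ± 0.21, adjusted p = 0.058 with the correction). With the correction 16 members rose and none fell (16 and 1 adjusted over the list alone) with a median of 3.21 (camera adjusted p = 2.9e-05, adjusted p = 0.479 with an estimated correlation). Ighm then had 4.04 ± 0.37, Igj 5.50 ± 0.42 and Igkc, a gene of 323 bp, 1.73 ± 0.16.

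The IgG genes Ighg1, Ighg3 and Ighg2c rose with wide spread between mice. Ighg1 rose from 0.445 ± 0.196 to 112 ± 148 CPM (7.96 ± 1.19, adjusted p = 4.7e-05), with 23.0, 30.4 and 283 CPM in the 24-month mice. Ighg3 rose from 0.390 ± 0.341 to 113 ± 153 CPM (8.18 ± 1.43, adjusted p = 0.00025), and Ighg2c from 3.76 ± 5.15 to 214 ± 29.4 CPM (5.86 ± 1.41, adjusted p = 0.0030). These genes are close paralogs on chromosome 12, and how reads shared among them were assigned is not given in the sources used here. Of 65 heavy chain V segments 62 rose (62 adjusted over the list alone, median 4.12), and of 65 kappa V segments 56 rose (56 adjusted over the list alone, median 2.94). With the correction 39 heavy chain and 24 kappa V segments rose, with medians of 2.31 and 1.05.

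**Figure D2:**
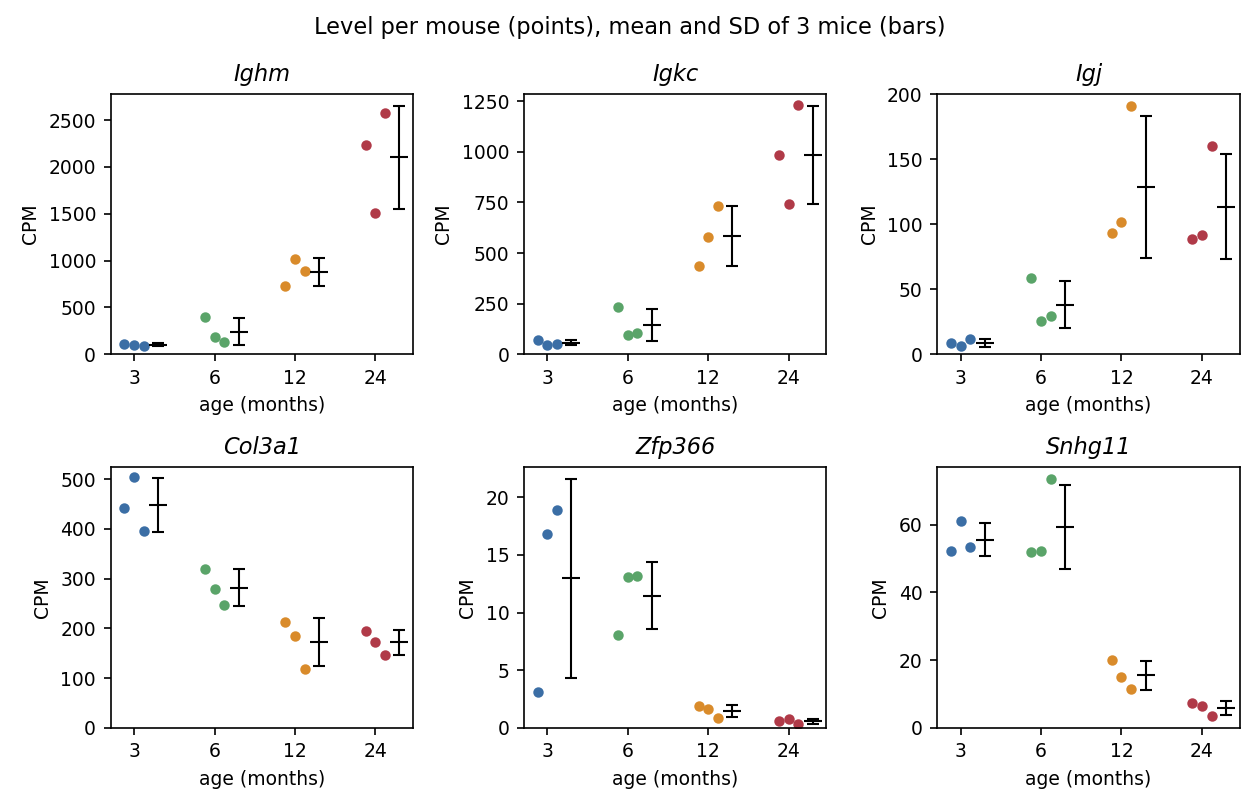
CPM (y axis) of 6 genes in each mouse by age (x axis, months), with points for mice and bars for mean and SD of 3 mice. Ighm went from 103 to 2106 CPM and Igkc from 57.6 to 985 CPM between 3 and 24 months, and Snhg11 from 55.5 to 5.77 CPM.

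Genes of antigen presentation also rose. H2-K1, a class I histocompatibility chain, went from 937 ± 183 to 4411 ± 712 CPM (2.23 ± 0.21, adjusted p = 2.3e-07). Tap1, a peptide transporter (3.10 ± 0.34), Psmb8, an immunoproteasome subunit (2.32 ± 0.23), and H2-Q6, a nonclassical class I chain (2.57 ± 0.29), rose as well. Of the 18 tested members 17 rose and none fell (17 adjusted over the list alone), with a median of 2.24 (camera adjusted p = 0.000159, adjusted p = 0.974 with an estimated correlation). The median GC content of these genes was 55.5%, on the side of the trend that was higher in the 24-month libraries. With the correction 16 rose (16 adjusted over the list alone) with a median of 0.91 (camera adjusted p = 0.000694, adjusted p = 0.796 with an estimated correlation), and H2-K1 had 0.64 ± 0.14.

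T cell genes and lymphoid chemokines passed camera over all mice with the correction and not without it. They passed fry without it (adjusted p = 0.00305 and 3.6e-05), as did 23 of all 46 lists, so a pass in fry is not particular to them. Without the correction the T cell list also passed camera in 1 of 6 fits with 1 mouse left out. Cd3e, a chain of the T cell receptor complex, rose from 4.66 ± 0.55 to 47.6 ± 22 CPM (3.34 ± 0.31, and 3.56 ± 0.34 with the correction). Cd6, a T cell coreceptor, rose by 3.68 ± 0.36 (1.74 ± 0.27 with the correction). Of 18 T cell genes 11 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.0781), and with the correction 11 rose and 1 fell (11 and 1 adjusted over the list alone) with a median of 0.77 (camera adjusted p = 0.0332, adjusted p = 0.983 with an estimated correlation). Of 6 T cell receptor V segments 2 rose (0 adjusted over the group alone, median 0.39), and with the correction none rose and 2 fell (median -0.848). Ccl19, which draws lymphocytes to lymphoid tissue, rose by 4.37 ± 0.50 (2.93 ± 0.36 with the correction), and Ltb, which organises such tissue, by 3.52 ± 0.45 (1.18 ± 0.23). Of 9 lymphoid organising genes 6 rose (6 adjusted over the list alone, camera adjusted p = 0.276), and with the correction 6 rose (7 adjusted over the list alone, camera adjusted p = 0.0378, adjusted p = 0.479 with an estimated correlation). Cxcl13, a B cell attractant, had 0.79 ± 0.48 (adjusted p = 0.13), and 2.34 ± 0.44 with the correction (adjusted p = 0.00046). Of 17 B cell genes 9 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.443), among them Spib, a transcription factor of B cells (3.47 ± 0.46), and Blk, a B cell kinase (2.80 ± 0.37). With the correction 9 B cell genes rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.115).

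The balance of collagen genes at 24 months depended on the correction. Col3a1 (chr1:45311538-45349706), the type III collagen chain, fell from 447 ± 54.8 to 172 ± 24.6 CPM (-1.38 ± 0.23, adjusted p = 5.0e-05, -1.64 ± 0.15 with the correction). Lox, which crosslinks collagen, fell (-3.73 ± 0.31, -1.08 ± 0.16 with the correction), as did Col5a2, a type V collagen chain, from 89.2 ± 13.1 to 22.2 ± 2.2 CPM (-0.64 ± 0.17 with the correction). Of 20 fibrillar collagen and crosslinking genes 11 rose and 8 fell (11 and 8 adjusted over the list alone, camera adjusted p = 0.761), and with the correction 3 rose and 12 fell (3 and 12 adjusted over the list alone, camera adjusted p = 0.0378, adjusted p = 0.796 with an estimated correlation). Col1a1, the type I collagen chain, had 1.57 ± 0.31 (adjusted p = 0.00021) without and -0.56 ± 0.16 (adjusted p = 0.0097) with the correction, and Eln, elastin, 1.81 ± 0.30 and -0.31 ± 0.13. Of 24 senescence and secretory genes 11 rose and 6 fell (11 and 6 adjusted over the list alone, camera adjusted p = 0.443), and with the correction 11 rose and 5 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.505). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 74.1 ± 9.5 to 293 ± 76.2 CPM (1.98 ± 0.24, adjusted p = 1.8e-06, 0.74 ± 0.18 with the correction). Cdkn2a, a senescence marker, had 1.70 ± 0.41 (adjusted p = 0.0013) without and -0.11 ± 0.37 (adjusted p = 0.82) with it. Mdm2, the p53 ubiquitin ligase, fell (-3.49 ± 0.22, -1.66 ± 0.12 with the correction), and Gdf15, a stress cytokine, rose (4.69 ± 0.44, 2.48 ± 0.31). Lmnb1, a nuclear lamina gene, had 0.22 ± 0.21 (adjusted p = 0.33) and -0.74 ± 0.13 (adjusted p = 0.00034) with the correction.

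The NRF2 and mitochondrially encoded lists passed camera as higher with the correction and not without it. Without it fry called 23 of 46 lists, among them the NRF2 list as higher (adjusted p = 0.0392) and the mitochondrially encoded list as lower (adjusted p = 0.00402). Gstm1, a glutathione transferase, rose from 440 ± 46.1 to 2404 ± 920 CPM (2.45 ± 0.25, 1.57 ± 0.17 with the correction). Gclc, which starts glutathione synthesis, fell from 190 ± 22.9 to 23.1 ± 9.1 CPM (-3.03 ± 0.28, -1.65 ± 0.18 with the correction). Of 22 NRF2 genes 10 rose and 9 fell (10 and 9 adjusted over the list alone, camera adjusted p = 0.761), and with the correction 13 rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.0217, adjusted p = 0.479 with an estimated correlation). Of 12 mitochondrially encoded genes, with a median GC content of 37.4%, 8 fell (8 adjusted over the list alone, camera adjusted p = 0.443), and with the correction 10 rose (10 adjusted over the list alone, camera adjusted p = 0.0119, adjusted p = 0.479 with an estimated correlation). mt-Co1, a cytochrome oxidase subunit, had -1.18 ± 0.23 without and 0.71 ± 0.21 with the correction. Sftpc, the surfactant protein of type 2 cells, had 0.57 ± 0.18 (adjusted p = 0.0078, 0.35, adjusted p = 0.138 without 3-month mouse 3) and -0.36 ± 0.11 (adjusted p = 0.012) with the correction. Scgb1a1, the club cell secretory protein, had 0.02 ± 0.32 (adjusted p = 0.96) and -1.34 ± 0.37 (adjusted p = 0.0085) with the correction.

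The genes with the largest falls at 24 months were mostly poor in GC. Phex (chrX:157162075-157415312), an endopeptidase, had 65 to 116 reads per library at 3 months and 0 reads in all 3 libraries at 24 months, where 3 reads would equal 0.167 to 0.204 CPM. Prrg4, a membrane protein, had 26 to 74 reads at 3 months and likewise 0 at 24 months. Slc10a5, a carrier of the bile acid family, had 234 reads at 3 months and 1 read at 24 months (ratio 0.00491, 95% counting interval 0.000124 to 0.0276). Uprt, Larp1b, Dtl and C1qtnf3 had 129 to 159 reads at 3 months and 1 read each at 24 months (ratios 0.00722, 0.00766, 0.00771 and 0.00890, with intervals reaching 0.0408, 0.0433, 0.0436 and 0.0505), and Veph1 had 229 and 2 reads (interval of the ratio 0.00121 to 0.0366). Atm, a DNA damage kinase, fell from 9.19 ± 3.08 to 0.160 ± 0.186 CPM (-5.68 ± 0.53, -2.88 ± 0.53 with the correction), and Clec12b, an inhibitory lectin, fell by 5.67 ± 0.55 (-3.93 ± 0.50). The GC content of these genes was 39.6 to 45.3%, except for Larp1b with 56.4%.

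Ecel1, an endopeptidase, had 1 read at 3 months and 161 at 24 months (ratio 185, 95% counting interval 32.7 to 7347). Dnase1l3, a nuclease of myeloid cells, rose by 5.28 ± 0.54 (6.86 ± 0.69 with the correction), and Grip2, a scaffold protein, by 5.01 ± 0.41 (2.89 ± 0.23). Mt3, a metallothionein, rose by 5.27 ± 0.77 (3.91 ± 0.72), and Cd5l, made by macrophages, by 5.14 ± 1.02 (4.72 ± 1.10). H19, an imprinted RNA, rose by 5.16 ± 1.15 with 2.39, 2.18 and 64.9 CPM in the 24-month mice, and with the correction and without 24-month mouse 3 it had 0.49 (adjusted p = 0.288). Lor, an epidermal barrier gene, had 0.738, 0.732 and 186 CPM in the 24-month mice (7.32 ± 2.08, adjusted p = 0.0087), and 0.93 (adjusted p = 0.113) without mouse 3. The Y-linked genes Ddx3y, a helicase (-3.65 ± 0.45), and Kdm5d, a histone demethylase (-3.20 ± 0.30), fell with Uty and Eif2s3y (4 of 4 fell, 4 adjusted over the list alone, median -3.15). With the correction 3 of the 4 fell with a median of -0.55, and Ddx3y had -1.19 ± 0.22. Xist, the X-inactivation RNA of female cells, had 0, 1 and 2 reads in the 24-month libraries and 0.526 to 0.666 CPM of all gene reads at 3 months.

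In all, 13277 of 16042 genes differed between 24 and 3 months (edgeR, adjusted p under 0.05), 6128 higher and 7149 lower. The authors' deposited table marked 13464 genes, 6448 higher and 7016 lower. With the correction 9006 genes differed, 4478 higher and 4528 lower. Of the 13277 genes, 45.5% (6045) were called in the same direction with the correction and 10.8% (1438) in the opposite direction.

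Some antibody genes were already raised at 12 months. Ighm rose from 103 ± 12.8 to 879 ± 148 CPM (3.09 ± 0.36, adjusted p = 0.00044, 2.90 ± 0.35 with the correction). Igj (chr5:88520512-88527891) rose from 8.84 ± 2.82 to 129 ± 54.3 CPM (3.87 ± 0.40, adjusted p = 0.00019, 3.94 ± 0.39 with the correction). Igkc (chr6:70726435-70726757) rose by 3.34 ± 0.36 (1.35 ± 0.16) and Igha by 1.96 ± 0.34 (1.63 ± 0.31). Of 18 plasma cell and immunoglobulin constant genes 9 rose and none fell (14 and 1 adjusted over the list alone), with a median of 1.72 (camera adjusted p = 2.1e-07, adjusted p = 0.445 with an estimated correlation). With the correction 8 rose (9 adjusted over the list alone), with a median of 1.48 (camera adjusted p = 1.5e-05, adjusted p = 0.422 with an estimated correlation). Of 65 heavy chain V segments 39 rose (46 adjusted over the list alone, median 2.42), and of 65 kappa V segments 46 rose (58 adjusted over the list alone, median 2.70). With the correction 11 heavy chain and 8 kappa V segments rose, with medians of 0.90 and 0.95. None of 17 B cell genes was called (0 adjusted over the list alone), and 1 of 18 T cell genes fell (1 adjusted over the list alone). With the correction 0 B cell genes were called and 4 T cell genes fell (0 and 4 adjusted over the list alone).

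Ighg2c rose by 4.78 ± 1.35 (adjusted p = 0.043), with adjusted p = 0.063, 0.071, 0.089 and 0.099 without 3-month mouse 1 or 2 or 12-month mouse 1 or 2. Ighg1 rose by 4.57 ± 1.12 (adjusted p = 0.023), with adjusted p = 0.097, 0.101, 0.063 and 0.074 without 3-month mouse 2 or 3 or 12-month mouse 1 or 2, and 0.067 with the correction. Ecel1 had 1 read at 3 months and 31 at 12 months (ratio 32.1, 95% counting interval 5.35 to 1308), with adjusted p = 0.127, 0.097, 0.050 and 0.081 without those same 4 mice.

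Among single genes at 12 months, Zfp366 (chr13:99184823-99247037), a repressor of dendritic cells, fell from 13.0 ± 8.6 to 1.46 ± 0.53 CPM (-3.12 ± 0.52, adjusted p = 0.0037, -3.14 ± 0.54 with the correction), with 3.10, 16.8 and 18.9 CPM in the 3-month mice. Hipk2, a p53 kinase, fell from 32.8 ± 25.1 to 5.74 ± 2.04 CPM (-1.98 ± 0.43 with the correction), with 7.44, 33.4 and 57.5 CPM in the same mice. Uprt, an enzyme of uracil salvage, fell by 2.78 ± 0.58 (adjusted p = 0.0092, 0.061 without 3-month mouse 2). Mpo, a neutrophil granule enzyme, fell by 2.54 ± 0.68 (adjusted p = 0.026, -2.82 ± 0.68 with the correction). Camp, a neutrophil antimicrobial peptide, fell by 2.29 ± 0.65 (adjusted p = 0.032, -2.95 ± 0.66 with the correction). Without 3-month mouse 1, 2 or 3 or 12-month mouse 1 or 2, the adjusted p of Mpo was 0.055, 0.107, 0.062, 0.091 and 0.073, and that of Camp 0.073, 0.122, 0.075, 0.107 and 0.072. Of 15 neutrophil genes 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.624).

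Some matrix and imprinted genes fell at 12 months. Col3a1 fell to 172 ± 48.3 CPM (-1.38 ± 0.23, adjusted p = 0.0040, -1.10 ± 0.15 with the correction), and Col5a2 from 89.2 ± 13.1 to 30.3 ± 7.4 CPM (-1.56 ± 0.21, -1.03 ± 0.17). Of 20 fibrillar collagen and crosslinking genes 1 rose and 3 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.174), and with the correction 1 rose and 6 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.00852, adjusted p = 0.6 with an estimated correlation). Col4a3, a basement membrane collagen, fell from 261 ± 87.8 to 81.9 ± 16.6 CPM (-1.67 ± 0.28, -0.93 ± 0.21 with the correction), and Nid1, nidogen, from 128 ± 23.0 to 56.7 ± 8.9 CPM (-1.17 ± 0.19, -0.66 ± 0.17). Of 18 basement membrane genes 8 fell (9 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 0.00335, adjusted p = 0.535 with an estimated correlation), and with the correction 6 fell (6 adjusted over the list alone, median -0.18, camera adjusted p = 0.0274, adjusted p = 0.625 with an estimated correlation). The imprinted growth genes Plagl1 (-1.59 ± 0.23), Meg3 (-1.93 ± 0.31) and Peg3 (-1.73 ± 0.34) fell. Of 10 such genes 6 fell (6 adjusted over the list alone), with a median of -0.85 (camera adjusted p = 0.0173, 0.133 without 12-month mouse 3, adjusted p = 0.445 with an estimated correlation). With the correction 5 fell (5 adjusted over the list alone, median -0.40, camera adjusted p = 0.0331, adjusted p = 0.422 with an estimated correlation).

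Some airway epithelial genes rose at 12 months. Scgb3a2, a club cell secretoglobin, rose from 897 ± 233 to 1831 ± 427 CPM (1.03 ± 0.23, 0.99 ± 0.14 with the correction), and Bpifa1, an airway defence protein, by 1.66 ± 0.42 (1.37 ± 0.44). Of 15 club and secretory genes 5 rose (7 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.0109, 0.0667 without 12-month mouse 2, 0.0509 with the correction, adjusted p = 0.535 with an estimated correlation). Foxj1, the regulator of motile cilia, rose from 119 ± 15.1 to 246 ± 36.9 CPM (1.05 ± 0.23, 0.53 ± 0.17 with the correction), and Tekt4, a tektin of cilia, by 1.32 ± 0.20 (0.83 ± 0.15). Of 15 ciliated cell genes 5 rose (5 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 0.00335, adjusted p = 0.535 with an estimated correlation), and with the correction 6 rose (8 adjusted over the list alone, camera adjusted p = 0.0212, adjusted p = 0.689 with an estimated correlation). The class II genes H2-Aa (0.88 ± 0.19) and H2-Eb1 (0.86 ± 0.24) rose. Of 18 antigen presentation genes 3 rose (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00249, adjusted p = 0.594 with an estimated correlation, 0.0578 with the correction).

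Some genes of respiration and protein folding rose at 12 months, and their lists passed camera with the preset correlation and not with an estimated one. Sdhb, a subunit of succinate dehydrogenase, rose by 0.82 ± 0.20, and of 35 nuclear oxidative phosphorylation genes 5 rose (22 adjusted over the list alone, camera adjusted p = 3.7e-07, adjusted p = 0.535 with an estimated correlation). With the correction 9 rose and 3 fell (13 and 4 adjusted over the list alone, median 0.24, camera adjusted p = 0.0105, adjusted p = 0.668 with an estimated correlation). mt-Co3, a cytochrome oxidase subunit, rose by 0.89 ± 0.21, and of 12 mitochondrially encoded genes 1 rose (1 adjusted over the list alone, camera adjusted p = 0.00423, adjusted p = 0.594 with an estimated correlation). Without 12-month mouse 3, whose mitochondrial share was 3.12%, the adjusted p was 0.133. With the correction 7 rose (9 adjusted over the list alone, camera adjusted p = 0.00011, adjusted p = 0.422 with an estimated correlation). Gpx2, a glutathione peroxidase, rose from 25.6 ± 3.6 to 51.2 ± 9.4 CPM (1.00 ± 0.19), and of 22 NRF2 genes 7 rose (9 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00304, adjusted p = 0.445 with an estimated correlation, 0.0081 with the correction and 0.422 with it and an estimated correlation). Calr, a chaperone of the endoplasmic reticulum, rose from 479 ± 39.9 to 876 ± 16.7 CPM (0.87 ± 0.18). Of 22 heat shock and unfolded protein genes 6 rose (10 adjusted over the list alone, camera adjusted p = 0.00331, adjusted p = 0.594 with an estimated correlation, 0.00961 with the correction and 0.689 with it and an estimated correlation).

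Some genes of heart muscle and fat also rose at 12 months. Myl4, an atrial myosin light chain, rose from 35.9 ± 13.2 to 98.6 ± 7.5 CPM (1.45 ± 0.34), and Nppa, the atrial natriuretic peptide, by 2.14 ± 0.61. Of 12 heart muscle genes 6 rose (8 adjusted over the list alone, median 1.05, camera adjusted p = 0.00147, adjusted p = 0.594 with an estimated correlation). Cidea, a lipid droplet protein, rose from 1.25 ± 0.24 to 6.59 ± 2.54 CPM (2.37 ± 0.42), and Ucp1, the uncoupling protein of brown fat, from 0.142 ± 0.064 to 2.68 ± 2.33 CPM (adjusted p = 0.042, and 0.059 with the correction). Of 11 adipose genes 4 rose (7 adjusted over the list alone, median 1.35, camera adjusted p = 0.00188, adjusted p = 0.594 with an estimated correlation). With the correction 4 heart muscle genes rose (9 adjusted over the list alone, camera adjusted p = 0.00852) and 3 adipose genes (5 adjusted over the list alone, camera adjusted p = 0.00961), and both lists had an adjusted p = 0.689 with an estimated correlation.

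**Figure D3:**
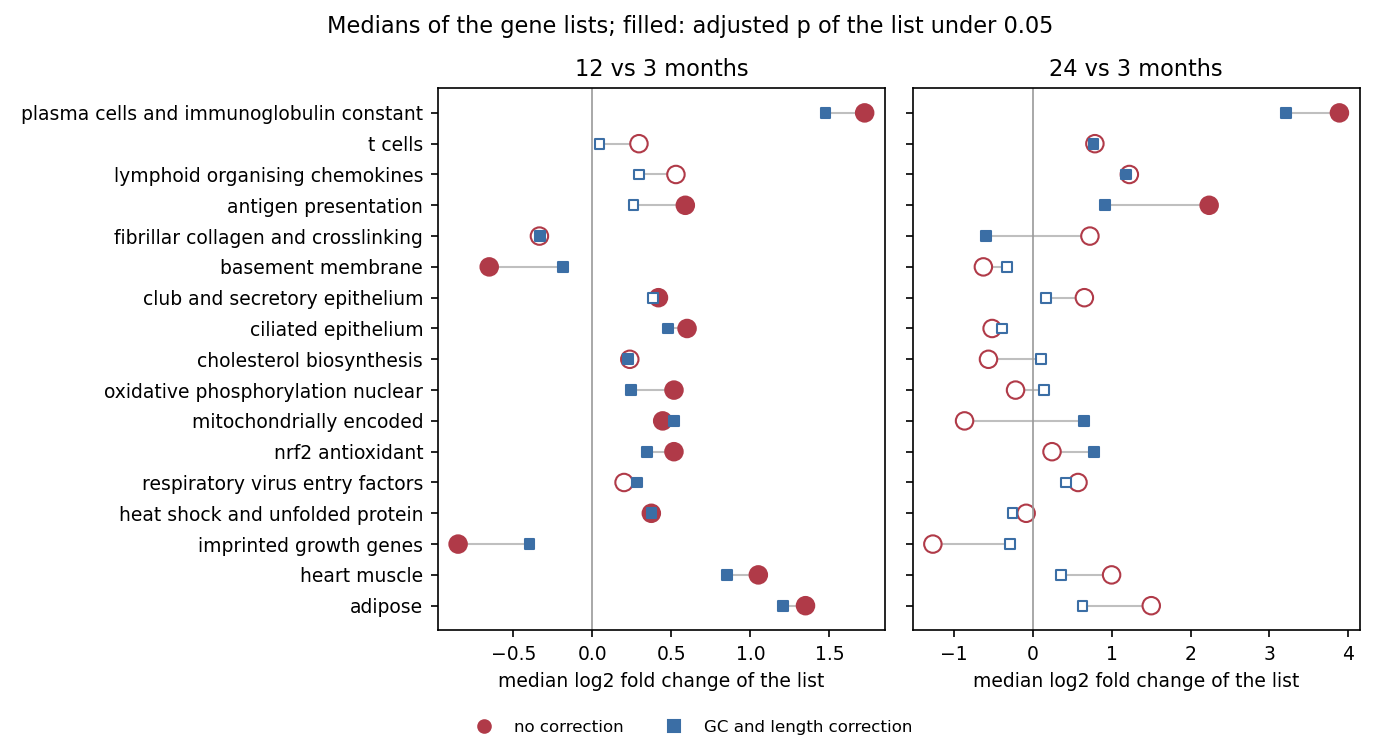
Median log2 fold change (x axis) of the members of 17 gene lists (y axis) at 12 and 24 against 3 months, circles without and squares with the correction, filled where the list test had an adjusted p under 0.05. Plasma cell genes had 1.72 and 1.48 at 12 months and 3.89 and 3.21 at 24 months, and mitochondrially encoded genes changed side at 24 months from -0.87 to 0.64.

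In all, 2433 genes differed between 12 and 3 months, 1010 higher and 1423 lower (3014 and 2723 without the 24-month libraries), and 2929 with the correction. The authors' deposited table marked 4653 genes, 2343 higher and 2310 lower. The count was 302 and 485 without 3-month mouse 2 or 3, and 1057 and 751 without 12-month mouse 1 or 2. With mouse number as a block 1587 genes were called, and Camp, H2-Eb1 and Ucp1 were not (adjusted p = 0.0503 to 0.0558). Without 3-month mouse 2, adjusted p was 0.0507 to 0.207 for 42 of the list members and fixed genes examined at this age, among them Foxj1, Scgb3a2, Sdhb, Calr, Gpx2, H2-Aa, Myl4, Nppa, Ucp1 and mt-Co3. Without 3-month mouse 3 this held for 34 genes (0.0511 to 0.183), without 12-month mouse 2 for 29 (0.0542 to 0.170), without 12-month mouse 1 for 19 (0.0512 to 0.173), without 12-month mouse 3 for 8 (0.0514 to 0.0897) and without 3-month mouse 1 for 7 (0.0539 to 0.102).

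At 6 months no gene had an adjusted p under 0.05 against 3 months with edgeR. Nr4a1 (chr15:101266846-101274792), an immediate early nuclear receptor, had 36.6 ± 8.0 CPM at 3 months and 88.6 ± 11.5 CPM at 6 months (1.28 ± 0.24, adjusted p = 0.30, 1.205 ± 0.15, adjusted p = 0.028 with the correction). Igj had 8.84 ± 2.82 and 38.0 ± 18.0 CPM (2.11 ± 0.38, adjusted p = 0.30). Fosb, an immediate early transcription factor, had 4.52 ± 1.49 and 25.6 ± 22.3 CPM, and Ighm 103 ± 12.8 and 239 ± 144 CPM. The unadjusted p was under 0.05 for 267 genes. DESeq2 called 6 genes (C130026I21Rik, Has1, Igj, Ighv1-53, Chia1 and Nr4a1, adjusted p = 0.00036 to 0.0104), limma voom called 0, and the authors' deposited table marked 20 genes. Without 6-month mouse 2, Ighv1-53 was called (adjusted p = 0.031).

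With the preset correlation 17 lists passed at 6 months, and with an estimated correlation or fry none did. Of 19 immediate early genes none was called (5 rose adjusted over the list alone), with a median of 0.47 (camera adjusted p = 5.1e-16, adjusted p = 0.118 with an estimated correlation). Of 18 plasma cell and immunoglobulin constant genes none was called (4 rose adjusted over the list alone), with a median of 0.70 (camera adjusted p = 1.8e-13, adjusted p = 0.118 with an estimated correlation). For 11 adipose genes (1 rose adjusted over the list alone), including Adipoq, a fat hormone, the median was 0.81 (camera adjusted p = 1.2e-06, 0.274 without 6-month mouse 1, adjusted p = 0.307 with an estimated correlation). For 10 platelet genes (0 adjusted over the list alone), including Pf4, a platelet chemokine, the median was -0.49 (camera adjusted p = 5.4e-05, adjusted p = 0.379 with an estimated correlation). For 8 erythroid genes (0 adjusted over the list alone) the median was -0.33 (camera adjusted p = 5.4e-05, adjusted p = 0.170 with an estimated correlation). For 18 antigen presentation genes (0 adjusted over the list alone) the median was 0.26 (camera adjusted p = 2.4e-05, 0.0706 without 3-month mouse 3, adjusted p = 0.379 with an estimated correlation).

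From 6 to 12 months Ighm, Igj and Igkc rose. Ighm rose by 1.88 ± 0.34 (adjusted p = 0.023, 1.69 ± 0.33 with the correction), Igj by 1.76 ± 0.37 (adjusted p = 0.033, 1.82 ± 0.35) and Igkc by 2.02 ± 0.34 (adjusted p = 0.023, 0.84 ± 0.16). Rhov, a small GTPase, rose by 1.57 ± 0.28 (adjusted p = 0.023), and Grip2 by 1.54 ± 0.36 (adjusted p = 0.043). Snhg11 (chr2:158375638-158386145), a long noncoding RNA, fell from 59.2 ± 12.4 to 15.5 ± 4.2 CPM (-1.93 ± 0.26, adjusted p = 0.0064, -1.40 ± 0.22 with the correction). Zfp366 fell by 2.95 ± 0.52 (adjusted p = 0.023), Ncam1, a neural adhesion molecule, by 1.94 ± 0.45 (adjusted p = 0.040), and the noncoding RNAs RP23-217K18.4 by 2.06 ± 0.46 (adjusted p = 0.038) and Dnm3os by 1.91 ± 0.43 (adjusted p = 0.038, 0.062 with the correction). Without 6-month mouse 3 all 10 genes had an adjusted p of 0.0608 to 0.218. Without 6-month mouse 2 this held for 9 of them (0.0636 to 0.117), without 12-month mouse 2 for 9 (0.0863 to 0.136), without 12-month mouse 1 for 8 (0.0512 to 0.123) and without 6-month mouse 1 for 5 (0.0578 to 0.137). With mouse number as a block only Igkc (adjusted p = 0.034) and Snhg11 (adjusted p = 0.017) were called, and the other 8 genes had an adjusted p of 0.05004 (Ighm, Igj, Rhov and Zfp366) to 0.0818.

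In all, 325 genes differed between 12 and 6 months, 77 higher and 248 lower (429 and 497 with the correction, 656 and 924 with DESeq2). More genes were higher than lower without the 24-month libraries (1713 and 1454), with the correction as well (1207 and 1056), with only the 6 mice (1229 and 986) and with mouse number as a block (11 and 6). The count was 926 with the correction, 1580 with DESeq2, 653 with limma voom, 3 without 6-month mouse 3 and 1172 without 12-month mouse 3.

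From 12 to 24 months most antigen presentation genes rose. H2-Q7, a nonclassical class I chain, rose from 121 ± 8.5 to 602 ± 223 CPM (2.31 ± 0.29, 0.70 ± 0.19 with the correction), H2-Q6 by 2.27 ± 0.28 (1.21 ± 0.19) and Tap1 by 2.53 ± 0.33 (0.85 ± 0.20). The H2-Q genes are close paralogs. Of 18 members 16 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 1.68 (camera adjusted p = 0.000519, adjusted p = 0.998 with an estimated correlation), and with the correction 14 rose (15 adjusted over the list alone, median 0.67, camera adjusted p = 0.00273, adjusted p = 0.865 with an estimated correlation). Mzb1 rose from 11.5 ± 0.9 to 78.4 ± 48.4 CPM (2.76 ± 0.36, 2.34 ± 0.29). Of 18 plasma cell genes 11 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0770), and with the correction 12 rose (14 adjusted over the list alone, median 1.64, camera adjusted p = 0.00555, adjusted p = 0.865 with an estimated correlation). Of 18 T cell genes 10 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0637), and with the correction 10 rose (10 adjusted over the list alone, median 0.74, camera adjusted p = 0.00202, adjusted p = 0.865 with an estimated correlation).

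Most ciliated cell genes fell from 12 to 24 months. Tekt1, a tektin, fell from 35.9 ± 4.9 to 12.8 ± 3.7 CPM (-1.48 ± 0.23, -1.58 ± 0.19 with the correction), and Ccdc113, a centriole protein, from 26.1 ± 8.2 to 5.50 ± 1.34 CPM (-2.23 ± 0.27, -1.38 ± 0.21). Of 15 members 3 rose and 10 fell (3 and 10 adjusted over the list alone, camera adjusted p = 0.663), and with the correction 1 rose and 10 fell (1 and 10 adjusted over the list alone, median -0.62, camera adjusted p = 0.00856, adjusted p = 0.865 with an estimated correlation). Mcm2, a replication helicase subunit, rose by 1.69 ± 0.24 (0.30 ± 0.12 with the correction) and Tyms, which makes thymidylate, fell by 1.60 ± 0.21 (-0.39 ± 0.19). Of 26 proliferation genes 10 rose and 13 fell (10 and 13 adjusted over the list alone, camera adjusted p = 0.990), and with the correction 11 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.0226, adjusted p = 0.865 with an estimated correlation).

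Among single genes, Ighg3 rose by 5.16 ± 1.17 from 12 to 24 months, Cd5l by 4.98 ± 1.01, H19 by 4.57 ± 1.11 and Atp2a1, the calcium pump of fast muscle, by 4.23 ± 0.86. Atp2a1 had 1.03 (adjusted p = 0.055) with the correction and without 24-month mouse 3, and Lor, at 7.29 ± 2.10, had 0.92 (adjusted p = 0.124) without that mouse and 5.286 (adjusted p = 0.055) with mouse number as a block. Phex and Prrg4 went from 0.825 ± 0.410 and 0.974 ± 0.132 CPM at 12 months to 0 reads. C1qtnf3, Slc10a5 and Dtl went from 92, 80 and 54 reads to 1 read each (ratios 0.0121, 0.0139 and 0.0205, with 95% counting intervals reaching 0.0689, 0.0795 and 0.119). In all, 12791 genes differed between 24 and 12 months, 5976 higher and 6815 lower, and 6864 with the correction.

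Over all ages 13567 genes differed (9102 with the correction), and 11615 genes were called for a slope on log2 age (7743 with the correction). Without the 24-month libraries the counts were 4210 and 5551. A slope does not show a steady change with age, since a step at 24 months can also give it. Fold changes from 3 to 6 months and from 12 to 24 months had a Pearson r of 0.22 over 16042 genes that are not independent. It was 0.07 with the correction, and 0.08 to 0.28 without it when 1 mouse was left out. Igj had 8.84, 38.0, 129 and 113 CPM at the 4 ages, and Zfp366 13.0, 11.5, 1.46 and 0.552 CPM.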

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

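The correction for GC content and length, the settings without the 24-month libraries and the combinations of these were chosen only after the results were seen. Alternatives written for a table without counts were not run. Counts of called genes held within a factor of 1.5 except as follows, and the causes of single shifts were not tested. At 24 against 3 months the count of 13277 became 8564 with the correction and without 24-month mouse 3. It was 9006 with the correction alone, within that factor, and 12827 to 13248 with 1 mouse left out. At 12 against 3 months 2433 became 1587 with mouse number as block, 3784 with the correction for GC alone, 5737 without the 24-month libraries, 4602 with the correction and without them, and 3962 with only the 6 mice, with 302 (3-month mouse 2 left out) to 3426 (12-month mouse 3 left out). At 6 against 3 months 0 became 6 with DESeq2, 2 without filter, 1 with GC alone, 1 with the correction and 1 with only the 6 mice, with 0 to 1 over mice left out. At 12 against 6 months 325 became 187 with RLE, 1580 with DESeq2, 653 with voom, 17 with the block, 1851 with GC alone, 926 with the correction, 3167 without the 24-month libraries, 2263 with the correction and without them, 2215 with only the 6 mice, and 625 with the correction and without 12-month mouse 3, with 3 (6-month mouse 3 left out) to 1172 (12-month mouse 3 left out). At 24 against 12 months 12791 became 7107 with GC alone, 6864 with the correction, and 6433 and 6329 with it and without 12-month or 24-month mouse 3. Over any age 13567 became 4210 without the 24-month libraries, 3337 with the correction as well, and 8859 with the correction and without 12-month mouse 3. The trend count of 11615 became 7743 with the correction, 5551 without the 24-month libraries, 4280 with both, and 6946 with the correction and without 24-month mouse 3. Lists called at 24 against 3 months (2) became 7 with the correction, 23 with fry and 0 with an estimated correlation, with or without the correction. At 12 against 3 months (12) and 6 against 3 months (17) an estimated correlation left 0, with or without the correction, and fry left 0 at 6 months. At 24 against 12 months (1) there were 5 with the correction, 23 with fry, 0 with an estimated correlation, with or without the correction, and 1 to 3 (12-month mouse 3 left out) over mice left out. The early and late r of 0.22 became 0.1092 with GC alone and 0.0685 with the correction, and 0.0814 (6-month mouse 2 left out) to 0.2797 (6-month mouse 3 left out).

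Directions of called genes at 24 against 3 months turned, in order with GC alone, with the correction, and with the correction and without 24-month mouse 3, for Cdkn2a (-0.3989, -0.1087, -0.1761), Col1a1 (-0.4609, -0.5564, -0.503), Eln (-0.2556, -0.3113, -0.4031), Sftpc (-0.677, -0.3615, -0.3122), mt-Cytb (1.377, 0.4101, 0.3074), mt-Co1 (1.493, 0.7137, 0.3332) and mt-Nd4 (1.182, 0.5817, 0.5687). mt-Co2 turned with GC alone (1.114) and with the correction without 24-month mouse 3 (0.06395), Ccl21a with GC alone (-0.2818), Xist with the correction (0.2718, and 0.5439 without 24-month mouse 3), and Lor with the correction without that mouse (-0.8228, and -0.2547 against 12 months). At 24 against 12 months Pcna turned with GC alone (0.03939), and Mcm4 with GC alone (0.137), with the correction (0.2827) and with it and without 12-month (0.2312) or 24-month mouse 3 (0.09886).

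Other splits of the mice into groups of 3 were counted too. For the pairwise comparisons 10 splits are too few for a share under 0.05. The real split gave 13277, 2433, 0, 325 and 12791 genes, and the highest other split 0, 0, 1, 1 and 0, so that 1, 1, 10, 1 and 1 of 10 splits gave as many genes as the real split. For any age 1 of 100 splits, the real split, gave 13567 genes and the highest other 12271. For the trend these were 11615 and 3833, again 1 of 100. The any-age splits with 12271 and 12199 genes kept the 24-month mice together under another age. The any-age count thus shows mainly that the 24-month libraries differ as a group, and not why.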

Other observations

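The tests of the GC and length trend as a source of the 24-month difference, of lymph node tissue at 24 months and of female mice were chosen only after the results were seen. The other tests of causes below, apart from that of read depth, used values with the correction, which was also added after the data were seen.

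Endothelial genes split at 24 months. Vwf, which binds platelets to the vessel wall, rose from 574 ± 114 CPM at 3 months to 5840 ± 2900 CPM at 24 months (log2 3.35 ± 0.34, n = 3, 1.79 ± 0.19 with the correction), and Eng, a TGF-beta coreceptor, rose by 2.69 ± 0.28 (0.75 ± 0.12). Ednrb, an endothelin receptor, fell from 90.6 ± 2.8 to 7.14 ± 3.56 CPM (-3.64 ± 0.35, -1.10 ± 0.19), and Tek, the angiopoietin receptor, fell by 3.11 ± 0.33 (-1.20 ± 0.21). Of 19 endothelial genes 11 rose and 6 fell (11 and 6 adjusted over the list alone, camera adjusted p = 0.37), and with the correction 7 rose and 6 fell (7 and 8 adjusted over the list alone).

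Some clock genes and most ribosomal protein genes were called at 12 months. Per3, a clock repressor, fell from 101 ± 18.5 to 38.2 ± 19.2 CPM (-1.41 ± 0.31, -1.09 ± 0.19 with the correction), and Ciart, another clock repressor, by 1.01 ± 0.26 (-1.19 ± 0.22). Without 3-month mouse 2 neither was called, nor was Ciart without 3-month mouse 1 or Per3 without 3-month mouse 3. Of 18 clock genes 5 fell (1 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.344). The time of day of tissue collection is not given. Of 77 ribosomal protein genes 53 rose (68 adjusted over the list alone) with a median of 0.72, and with the correction 33 rose and 2 fell with a median of 0.34. At 24 against 3 months 25 of them rose and 25 fell (24 and 33 with the correction). From 12 to 24 months 12 rose and 45 fell (17 and 43 with the correction).

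The breadth of the 24-month difference may come in large part from a trend on GC content and gene length, since a smooth of both gave 74.55% of the variance of the fold changes. This share cannot separate a technical trend from an effect of age that itself follows GC content or length. The correction would remove such an age effect too. Whether the trend is the whole cause stays open. With the correction 45.5% of the calls were still made in the same direction and 10.8% in the opposite one. No test here separates the rest from a trend left in part. Lower read depth is excluded as the cause, since thinning all libraries to 14713705 reads gave 99.5% as many calls. Whether the trend arose in RNA, library preparation or sequencing could not be tested, since no batch, date or RNA integrity value is given.

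Plasma cells may accumulate in the lung with age, since their genes passed the list test with the correction at 12 and 24 months (the higher adjusted p was 2.9e-05). The estimated correlation gave adjusted p = 0.422 and 0.479, so this stays a hypothesis. A corrected list median of 1.48 at 12 months (quartiles 0.48 to 2.52) argues against the GC and length trend as the whole cause. The medians of V segments went from 2.42 to 0.90 (heavy chain) and from 2.70 to 0.95 (kappa) with the correction. The smooth was fitted on genes with a mean CPM of at least 1, and V segments that reached this were among them. Their lower medians thus cannot show how much of their rise came from the trend. Lymph node tissue is argued against at 12 months by a corrected T cell median of 0.0451 (quartiles -0.34 to 0.38). This does not cover other tissue next to the lung, and the heart muscle and adipose lists also rose at 12 months with the preset correlation. At 24 months the corrected T cell median of 0.7685 and B cell median of 0.82 leave lymph node tissue open. The median over 6 T cell receptor V segments was 0.39 without and -0.848 with the correction. Since its sign depends on the correction, it does not decide the question.

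The fall of Y-linked genes at 24 months may come mostly from the GC and length trend, since their median of -3.15 became -0.5512 with the correction. Loss of the Y chromosome in some cells stays open for the rest. With the correction 3 of the 4 genes still fell, but the 4 values were uneven, from -1.19 to -0.10. No test here separates such a loss from a trend left in part. Female mice are argued against by Xist, which showed no rise, with at most 0.1114 CPM at 24 months against 0.526 to 0.666 CPM at 3 months, and a log2 fold change of 0.27 ± 0.77 (adjusted p = 0.79) with the correction. Ddx3y still had 73, 95 and 12 reads in the 24-month mice.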
